A study of Homo sapiens with 6 samples.

How the data were processed

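Total RNA from Hep 3B cells, an established human hepatoma line, was analysed on 6 Affymetrix expression arrays, 3 from cells with CMTM4 knockdown and 3 from control cells. Per the labels' protocols, RNA was extracted with Trizol, checked with a NanoDrop spectrophotometer, and 100 ng of it was turned into biotin-labelled cRNA. The labels describe the knockdown in more than 1 way. The series design speaks of lentiviral short hairpin RNAs and a control virus, the treatment protocol speaks of transfection of short hairpin RNAs with a lipid reagent, and the sample descriptions use an abbreviation for knockout where titles and genotype say knockdown. The sequences and the number of the hairpins, and the time between delivery and harvest, are not given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

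The authors deposited 1 table of log2 expression values per probe set (a set of short oligonucleotides for 1 transcript or group of transcripts), with 1 column per array. MAS5 is named, per the submitters' processing notes, with no role and no version. Background correction, summarisation and normalization are not given in the sources used here. The base of the logarithm was inferred from the values: they reached 14.75, above 11.09, the natural logarithm of the largest 16-bit scanner reading, and below 16, its base 2 logarithm. The array medians lay between 6.73 and 6.75, so the deposited values were taken as already scaled between arrays, by a method that is not stated, and were kept in that scaling. Such scaling sets the arrays to a common level, so a change shared by most transcripts is not visible in it. The tests planned for a log2 table were therefore used, with no pseudocount. The table holds no detection calls, and the precision is limited by the number of arrays.

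Probe sets were named through the platform annotation supplied with the table. Of 49395 probe sets, 44994 had 1 gene symbol, 1832 had several and 2569 had none. Gene identifiers of 44967 of the probe sets with 1 symbol matched the RefSeq gene table of GRCh38.p14, which was used for names and for the order of neighbouring genes alone, and 0 symbols changed. Probe sets with several symbols named no gene. Each of 18132 genes was represented by the probe set with the highest mean over the 6 arrays among those naming that gene alone. Genes were tested when this probe set lay above the 40th percentile of its array in at least 3 of 6 arrays, which kept 11488 genes and left out 6644. Where a chosen probe set has a suffix of the form _s_at or _x_at, its probes can match several transcripts, which held for 70 of the 162 genes named by the rule given further on. Of these 162 genes, 120 had more than 1 probe set above the filter. For 99 of the 120 all such probe sets passed the test in the direction of the chosen one.

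Knockdown was compared with control by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the 11488 genes and a threshold of 0.05 on the adjusted p. Rose, fell and changed are used of genes past that threshold. Log2 changes are knockdown minus control. For CMTM4 a two-sided exact permutation test was added. A total of 39 gene lists with 1014 memberships, of which 939 had a probe set naming the gene alone, were written from general knowledge. Lists with at least 5 tested genes were compared with the other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over 36 lists. The same test with a correlation estimated per list and limma's fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were run as alternatives. Markers of fibroblasts, endothelial cells, leukocytes and the embryonic kidney line HEK293 were among the lists.

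The genes named were fixed by a rule. It takes CMTM4, CMTM6 and CD274, and the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between groups and whose higher group mean exceeded the median of the tested genes, passing over provisional symbols. From each list that was called or had at least 3 genes past the threshold, it takes up to 4 genes with the largest absolute change. Other list members and neighbouring genes are named in places, and those were chosen after their values were seen. The groups, the tests, the lists, the rule for names and the first set of alternative settings were fixed before the data were examined.

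The alternative settings of that set were quantile normalization, median centring, no filter, a filter at the 60th percentile, all probe sets tested on their own, the mean over the probe sets of a gene, eBayes without trend and with robust estimation, array weights, the replicate number as a block, leaving out each array in turn, an adjusted p under 0.01, a change of at least 2-fold, and the other list tests. Pseudocount alternatives were planned for a linear table and did not apply. Centring on the poly-A spike-in probe sets, unshared probe sets only and limma's treat against a 1.2-fold change were added after the data had been seen. The poly-A spike-ins are bacterial transcripts with poly-A tails that are mixed into the RNA before labelling in the standard protocol. The labels do not state how or when they were added, so a lower spike-in signal can stand for less spike-in or for more cellular RNA per labelling.

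The fit was tested on simulated data made from the 11488 tested genes, with 200 genes changed in each of 5 draws. Changed genes were called in the right direction in 67.2% of cases at a log2 change of 0.25, in 96.4% at 0.5, in 99.6% at 1 and in 100% at 2. False calls made up 48 of 1039 calls (4.62%). A list of 30 further genes, all shifted upward by the same amount, was called in 5 of 5 draws, and 0 of 175 unchanged lists were called. Most lists in the data held genes that moved in both directions, so the 5 of 5 does not show how often such lists are found. Noise was drawn independently for each gene, so the list counts do not show how often lists of correlated genes are falsely called. Far fewer genes were changed than the 6452 called in the data. The cutoff on p depends on that number, so the recovery in the data may differ. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.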

Results

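Expression was measured in 6 samples of Hep 3B hepatoma cells, 3 with knockdown of CMTM4 by short hairpin RNA and 3 controls. CMTM4 encodes a multi-pass membrane protein of the CMTM family. The series title places the question in hepatocellular carcinoma, and the design implies 1 comparison, knockdown against control. Array medians ran from 6.73 to 6.75 on the log2 scale. Correlations across probe sets, which are not independent replicates, were 0.9985 to 0.9988 between arrays of 1 group and 0.9945 to 0.9951 between arrays of different groups.

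CMTM4 was 6.34-fold lower in the knockdown. Its brightest probe set read 9.43 ± 0.07 (SD, n = 3) in control and 6.77 ± 0.16 (SD, n = 3) in knockdown cells, a log2 change of -2.66 (SE 0.068, limma adjusted p = 4.25e-12). Every knockdown array lay below every control array, and the exact permutation test gave p = 0.1, the smallest p that 3 against 3 arrays allow. A further CMTM4 probe set above the filter changed by -2.22, a size that is uncertain because its knockdown mean of 5.92 lay near the 40th percentile of the arrays (5.84 to 5.88), and the third, at 4.04 in control and 3.45 in knockdown cells, lay below the filter and differed by -0.59. CMTM6, the family member known with CMTM4 as a stabiliser of PD-L1 protein, read 11.34 ± 0.0060 in control and 11.24 ± 0.0028 in knockdown cells (SD, n = 3), a log2 change of -0.09 (adjusted p = 0.00235), which became 0.07 (adjusted p = 0.0554) with the arrays centred on their poly-A spike-ins. CD274, which encodes PD-L1, was too dim to be tested, at 4.98 ± 0.08 in control and 5.04 ± 0.10 in knockdown cells (SD, n = 3).

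In the CMTM family list, 0 members rose and 4 of 6 tested members fell, both over all genes and adjusted over the list alone. CMTM3, which lies beside CMTM4 on the chromosome, fell 1.83-fold, from 11.28 ± 0.02 to 10.40 ± 0.08 (SD, n = 3; log2 change -0.87, SE 0.036, adjusted p = 3.40e-10), and its other probe set changed by -0.89. CMTM8 changed by -0.11, CMTM7 read -0.0033 and CMTM5 read -0.04, the last 2 without passing the test. The list had a median of -0.10 and passed camera with adjusted p = 0.0179 (adjusted p = 0.232 with an estimated correlation), and with poly-A spike-in centring its median turned to 0.061 (1 higher, 2 lower) and CMTM8 turned to 0.053 (adjusted p = 0.177). The list holds the target itself, and without CMTM4 the adjusted p was 0.0898. On the other side of CMTM4, its nearest tested neighbour DYNC1LI2, a dynein subunit gene, was lower on all of its 6 probe sets, by -0.47 to -0.90, while the next tested genes outward, TK2 and NAE1, changed by -0.01 (not past the test) and 0.21.

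**Figure D1:**
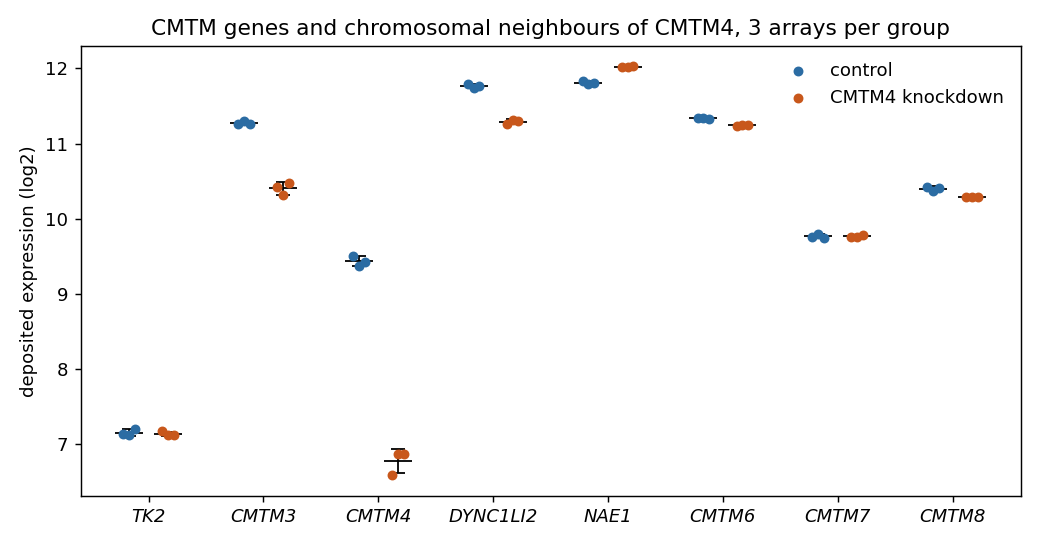
Deposited log2 expression of CMTM genes and of the chromosomal neighbours of CMTM4 in 3 control and 3 knockdown arrays; points are arrays, long lines group means and error bars SD. CMTM4 fell from 9.43 to 6.77 and CMTM3 from 11.28 to 10.40, whereas the small differences of CMTM6 (-0.09) and CMTM8 (-0.11) changed sign with poly-A spike-in centring.

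The largest fall was that of LOX, the lysyl oxidase that crosslinks collagen and elastin. LOX was 7.22-fold lower, at 10.80 ± 0.04 in control and 7.95 ± 0.06 in knockdown cells (SD, n = 3), a log2 change of -2.85 (SE 0.038, adjusted p = 1.97e-14), with all 6 of its probe sets lower. LTB, which encodes the cytokine lymphotoxin beta, changed by -1.88 on the log2 scale, NPPB, the precursor of the natriuretic peptide BNP, by -1.78 and DEFB1, an epithelial defensin, by -1.64. HMGCS1, the cytosolic HMG-CoA synthase of cholesterol synthesis, changed by -1.63. The remaining genes of the 12 largest falls besides CMTM4 were DPY19L1 (-1.83), SMIM13 (-1.79), CDK2AP1 (-1.71), CYSTM1 (-1.66), C1D (-1.62) and METAP2 (-1.60). For SMIM13, 2 of 3 probe sets above the filter passed in that direction.

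CHODL, which encodes the membrane lectin chondrolectin, led the rises by the rule for named genes, at 10.01 ± 0.03 in control and 11.60 ± 0.04 in knockdown cells (SD, n = 3; 3.00-fold, SE 0.028 on the log2 scale, adjusted p = 1.37e-13). GABRA2, a subunit of the GABA-A receptor, rose by 1.48, FAM3C, a secreted cytokine-like protein, by 1.43 and SSTR2, a somatostatin receptor, by 1.15. The transcription factor EGR1 rose by 1.12, the small GTPase RAP1A by 1.11 and TIMP1, an inhibitor of matrix metalloproteinases, by 1.06. Of the 4 RAP1A probe sets above the filter, 3 passed in that direction. SIPA1L2 (1.12), MANEA (1.12), IER3IP1 (1.08), TMT1B (1.08) and BTF3L4 (1.04) made up the 12. Adjusted p over these 24 genes ran up to 3.51e-10, and their arrays did not overlap between groups.

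**Figure D2:**
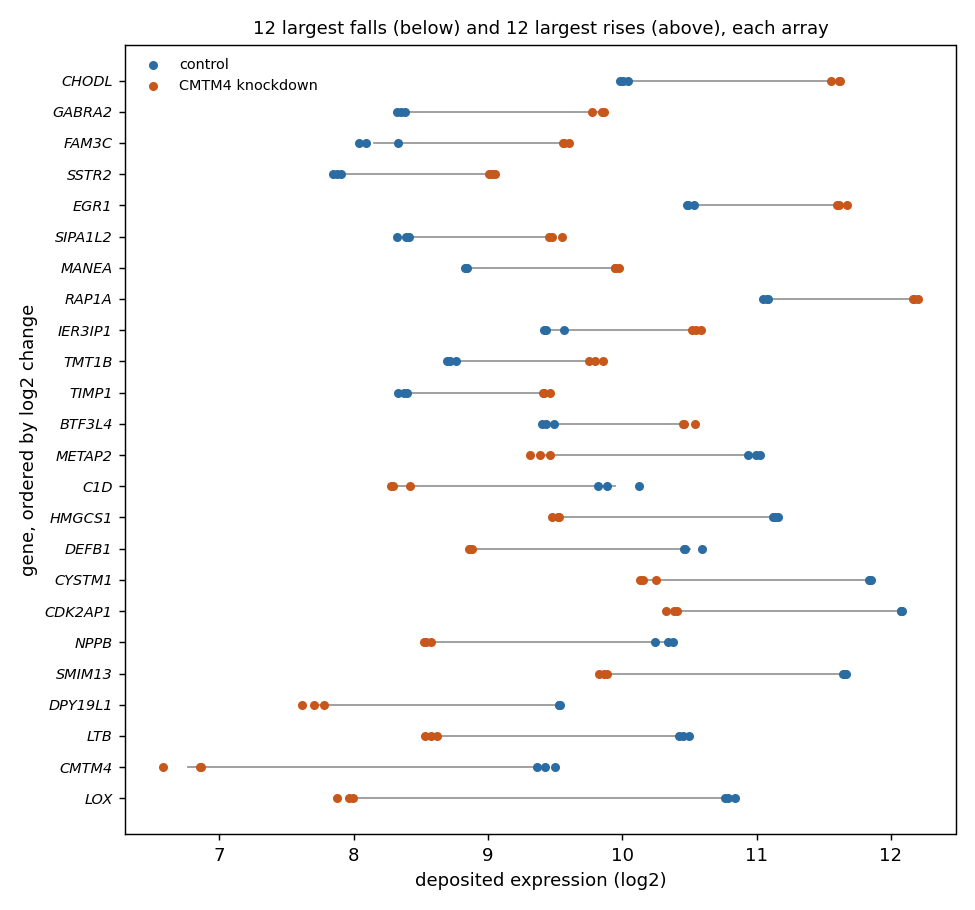
Deposited log2 expression (horizontal axis) of the 12 largest rises and 12 largest falls among genes with a higher group mean above the median of the tested genes; blue points are 3 control arrays, orange points 3 knockdown arrays, and grey lines join the group means. LOX (10.80 to 7.95) and CMTM4 (9.43 to 6.77) fell most, and CHODL (10.01 to 11.60) and GABRA2 (8.35 to 9.83) rose most by that rule.

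Across the genome, most changes were small. Of 11488 tested genes, 6452 (56.2%) changed at adjusted p under 0.05, 3553 higher and 2899 lower in the knockdown, and 3952 of these (61.3%) changed by less than 1.2-fold. The median change among them was 1.17-fold. A total of 497 genes changed by at least 1.5-fold (158 higher, 339 lower) and 126 by at least 2-fold (34 higher, 92 lower). The arrays of the groups did not overlap for 7174 genes (62.4%), against 10% by chance with 3 against 3 arrays. The threshold of a 2-fold change lowered the count from 6452 to 126, and a test against a 1.2-fold change gave 1255 genes (503 higher, 752 lower).

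The direction of small changes rested on the level to which arrays were scaled. The 24 poly-A spike-in probe sets read 8.02 ± 0.03 in control and 7.86 ± 0.0049 in knockdown arrays (SD, n = 3), a difference of -0.16 with 0 of 24 higher (exact permutation p = 0.1, the smallest possible). Centring the arrays on them moved the median change of all genes from 0.02 to 0.19, and the split became 7668 higher and 1272 lower, so that 85.8% of changed genes were higher against 55.1% as deposited. At 2-fold the split became 58 higher and 59 lower. The 18 hybridization spike-ins differed by -0.03, and the 3' minus 5' signal of actin was 0.158 ± 0.011 in knockdown and 0.139 ± 0.030 in control arrays (SD, n = 3; exact permutation p = 0.4). Background probe sets rich in G and C were higher by 0.12 in the knockdown, or by 0.075 without control 1.

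Of 36 gene lists tested, 10 passed camera with its preset correlation, 9 lower and 1 higher in the knockdown, and 0 passed with an estimated correlation, the smallest adjusted p being 0.0784. The estimate was below the preset 0.01 for NF-kB (-0.035), hypoxia (0.00034), MYC (2.5e-05), epithelial (-0.0075), YAP/TAZ (-0.020) and CMTM (-0.15) lists. A correlation above the preset thus does not account for the loss of those calls. For TGF-beta, ATF4, cholesterol and G2/M lists the estimate was higher, at 0.045 to 0.064. What else differs between both forms of the test was not examined. By fry, 29 lists passed. Unless another scaling is named, counts and medians refer to the deposited scaling. Where all probe sets were tested on their own, the probe sets of 1 gene entered a list as separate members. A list that passed in that setting thus counts repeat readings of the same genes. With poly-A spike-in centring, which shifts all genes alike, 9 of the 10 lists still passed camera.

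Targets of NF-kB and IL-17 signalling and chemokines fell as a list. Of 22 tested members 16 fell and 1 rose, the same counts as adjusted over the list alone, with a median of -0.22 (camera adjusted p = 3.30e-05, adjusted p = 0.0784 with an estimated correlation). The cytokine IL32 changed by -1.40 on the log2 scale, and the neutrophil-attracting chemokines CXCL6, CXCL5 and CXCL1 by -1.20, -1.12 and -0.71. CXCL8 (-0.58), NFKBIA (-0.44) and TNFAIP3 (-0.48) were also lower, as was TRAF3IP2 (-0.62), which encodes the IL-17 receptor adaptor Act1. The receptor genes IL17RA (0.01) and IL17RC (-0.04) did not pass the test. NFKBIZ was the 1 member that rose (0.36). With poly-A spike-in centring the median stayed below 0, at -0.055, and 10 members fell and 6 rose.

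Genes of the hypoxia response and glycolysis also fell as a list, with 21 of 30 lower and 3 higher, adjusted over the list alone likewise, and a median of -0.18 (camera adjusted p = 3.30e-05, adjusted p = 0.0784 with an estimated correlation). EGLN3, a hypoxia-induced prolyl hydroxylase, fell 2.84-fold (-1.51), NDRG1 by 0.90 and P4HA1, a collagen prolyl hydroxylase, by 0.72 on the log2 scale. PFKFB3, which makes an activator of phosphofructokinase, changed by -0.53 and VEGFA by -0.28. The glucose transporter gene SLC2A1 (0.32), HK2 (0.29) and GPI (0.27) rose. Centred on the spike-ins, the median of the list shrank to -0.016, with 12 lower and 10 higher.

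MYC targets and ribosome biogenesis genes rose as a list under each scaling, with 22 of 27 higher and 1 lower (22 and 1 adjusted over the list alone) and a median of 0.17 (camera adjusted p = 4.41e-05, adjusted p = 0.0784 with an estimated correlation). Poly-A spike-in centring gave 26 higher and 0 lower, with a median of 0.34. MYC rose from 11.71 ± 0.04 to 12.20 ± 0.04 (SD, n = 3; log2 change 0.48). POLR1B and POLR1A, subunits of RNA polymerase I, rose by 0.46 and 0.36, and the processing factor RRP9 by 0.43. PES1 was the 1 member that fell (-0.18). Ribosomal protein genes did not pass as a list (adjusted p = 0.462), with 3 of 31 higher and 4 lower over all genes and 2 and 2 adjusted over the list alone. With poly-A spike-in centring 29 of the 31 were higher and 0 lower. Their median of -0.0066 became 0.16, below the 0.19 of all tested genes with that centring.

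TGF-beta targets and YAP/TAZ targets were lower, 2 lists that share CCN2 and TGFB2. Of 19 genes of the TGF-beta list 13 fell and 3 rose (median -0.22, camera adjusted p = 7.35e-04, adjusted p = 0.232 with an estimated correlation). The list is not made of targets alone, since it also holds ligand and receptor genes. Of these TGFB2 (-0.22) and TGFBR1 (-0.41) fell, and TGFB1 (0.24) and TGFBR2 (0.17) rose, as did LTBP3 (0.12). KLF10 (0.05) and SKIL (-0.16) did not pass the test. CCN2, a matricellular growth factor gene induced by both pathways, fell 2.14-fold (-1.09), ID3 by 0.81, BHLHE40 by 0.61 and the inhibitory SMAD6 by 0.58 on the log2 scale. Of 22 YAP/TAZ targets 13 fell and 5 rose (median -0.19, camera adjusted p = 0.00892, adjusted p = 0.183 with an estimated correlation), with GADD45B at -1.21, AJUBA at -1.01 and ANKRD1 at -1.19, the last from 6.76 to 5.57, a knockdown level below the 40th percentile of each array (5.84 to 5.88), where the size of the change is uncertain. Counts adjusted over the list alone were the same for both. With poly-A spike-in centring 9 genes of the TGF-beta list were lower and 5 higher (median -0.061), against 8 YAP/TAZ targets lower and 9 higher (median -0.030).

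Epithelial junction and keratin genes fell as a list, 16 of 23 lower and 3 higher, adjusted over the list alone as well, with a median of -0.16 (camera adjusted p = 0.00107, adjusted p = 0.124 with an estimated correlation) that shrank to -0.00027 with poly-A spike-in centring, where 7 were lower and 7 higher. The desmosomal cadherin DSC2 changed by -1.24 on 6 of 6 probe sets in that direction, KRT19 by -0.76, KRT8 by -0.36 and the desmosomal plaque gene PKP2 by -0.35. CDH1, which encodes E-cadherin, changed by -0.29. Genes of mesenchymal cells and of the epithelial-mesenchymal transition, of which 6 of 15 fell and 2 rose (the same adjusted over the list alone), did not pass as a list (adjusted p = 0.111) unless all probe sets were tested, and their median of -0.047 became 0.12 with poly-A spike-in centring (8 higher, 3 lower). Apart from LOX, TAGLN (-1.21) and VIM (-0.36) fell, and FN1, which encodes fibronectin, rose by 0.18, with 1 of its 8 probe sets passing in the other direction.

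Cholesterol synthesis genes and ATF4 targets passed camera as lower. With poly-A spike-in centring, which shifts all genes alike, their medians turned positive, to 0.070 (9 higher, 4 lower) and 0.078 (14 higher, 6 lower). Both lists still passed camera with that centring, and both medians lay below the 0.19 of all tested genes. Of 19 cholesterol genes 10 fell and 3 rose (median -0.09, camera adjusted p = 0.0175, adjusted p = 0.276 with an estimated correlation). Beside HMGCS1, INSIG1, which encodes a brake on SREBP processing, changed by -1.26, IDI1 by -0.58 and LSS by -0.35. Of 28 ATF4 and amino acid response genes 14 fell and 4 rose, against 14 and 5 adjusted over the list alone, where the cholesterol counts did not differ (median -0.08, camera adjusted p = 0.00892, adjusted p = 0.254 with an estimated correlation). DDIT4 (-0.92) and SESN2 (-0.73) fell, while DDIT3, which encodes CHOP, rose by 0.76 and ATF4 itself read -0.02, not past the test. SLC7A11, the cystine transporter gene, read -1.11 on its chosen probe set, but -0.01 (adjusted p = 0.853) on the brightest of its probe sets without a shared suffix.

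Mitotic genes passed camera as lower in the deposited scaling, a call that was lost with poly-A spike-in centring. Of 46 G2/M genes 20 fell and 6 rose, adjusted over the list alone also, with a median of -0.066 (camera adjusted p = 0.0179, adjusted p = 0.341 with an estimated correlation). Centred on the spike-ins, the median was 0.097 with 24 higher and 5 lower, below the median of 0.19 over all tested genes. ECT2 and KIF23, which act in cytokinesis, changed by -0.83 and -0.56 and the anaphase activator CDC20 by -0.41, while the phosphatase CDC25A rose by 0.59. MKI67 (0.04), TOP2A (-0.03) and CDK1 (-0.04) did not pass the test. Of 41 G1/S and DNA replication genes 14 fell and 8 rose (the same adjusted over the list alone; list adjusted p = 0.317), among them RFC2 (-0.60) and MCM3 (-0.44) lower and CCND1 (0.57) and MCM6 (0.46) higher, and the median of -0.033 became 0.13 with that centring (26 higher, 4 lower).

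Lists tied to the tumour's contact with immune cells did not pass with the filter at the 40th percentile and 1 probe set per gene. Among 10 immune checkpoint ligands and related genes 7 fell and 2 rose (list adjusted p = 0.198), with VSIR, which encodes VISTA, at -0.54 (knockdown mean 5.94, near the 40th percentile of the arrays, so that the size is uncertain), TNFRSF14 at -0.36 and CEACAM1 at 0.45. For MHC class I antigen presentation 7 of 15 fell and 3 rose (adjusted p = 0.419), with the peptide transporter TAP1 at -0.40, its knockdown mean of 5.85 being near the 40th percentile of the arrays, and the chaperone CALR at 0.36. For the interferon response 7 of 18 fell and 2 rose (adjusted p = 0.0889), led by the RNA sensors IFIH1 (-0.57) and RIGI (-0.31) and by IFI35 (-0.40), and this list passed without a filter and with all probe sets tested. Adjusted over the list alone the counts of these 3 lists were the same, and with poly-A spike-in centring their medians of -0.12, -0.054 and -0.062 became 0.045 (4 higher, 2 lower), 0.11 (8 higher, 1 lower) and 0.10 (8 higher, 3 lower).

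Genes of hepatocyte function moved in part. Of 28 secreted hepatocyte proteins 16 rose and 6 fell (the same adjusted over the list alone; median 0.077, list adjusted p = 0.0889), and the list passed camera without a filter, with all probe sets and with poly-A spike-in centring, the last with 23 higher, 1 lower and a median of 0.24. APOH (0.34), AHSG (0.33), APOC1 (0.28) and ITIH2 (0.28) rose. ALB, which encodes albumin, read 14.71 in both groups, near the array maxima of 14.73 to 14.75, where a change might not be visible. TDO2, the hepatic tryptophan dioxygenase, rose 4.80-fold, from 5.49 ± 0.08, a level below the 40th percentile of each array (5.84 to 5.88), to 7.75 ± 0.23 (SD, n = 3; log2 change 2.26, adjusted p = 5.05e-10), on its 1 probe set. Its control level makes the size of that change uncertain. ADH4 (0.94, from a control mean of 5.86 near the same percentile), FOXA3 (0.50) and CYP1A1 (0.46) also rose, and the list of hepatocyte transcription factors and metabolism had 6 of 18 higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.419). Of 17 liver cancer and progenitor markers 7 rose and 7 fell (8 and 7 adjusted over the list alone, adjusted p = 0.810), with PEG10 (0.68) and LIN28B (0.56) higher and SOX9 (-0.56) lower. The median of this list, -0.018, turned to 0.14 with poly-A spike-in centring (10 higher, 4 lower). The medians of the 2 hepatocyte lists were positive under each scaling, and that of transcription factors and metabolism was 0.18 with poly-A spike-in centring (15 higher, 1 lower).

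Some markers of other cell types changed, in both directions in the deposited scaling. Of the fibroblast markers LUM changed by -0.88 (knockdown mean 5.99, near the 40th percentile of the arrays) and PDGFRA by 0.64 (2 of its 3 probe sets above the filter passing in that direction). Of the leukocyte markers CD14 changed by 0.54 and LYZ by -0.42, and the 6 tested leukocyte markers did not pass as a list (3 higher, 1 lower, adjusted p = 0.419). With poly-A spike-in centring 5 leukocyte markers were higher and 1 lower (median 0.34), and the list passed camera where all probe sets were tested on their own. The fibroblast list (4 tested, 2 higher, 2 lower), the endothelial list (3 tested, 0 higher, 2 lower) and the HEK293 list (2 tested, 1 higher, 1 lower) were too short for the list test. Counts adjusted over the list alone were the same for all 4 lists.

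**Figure D3:**
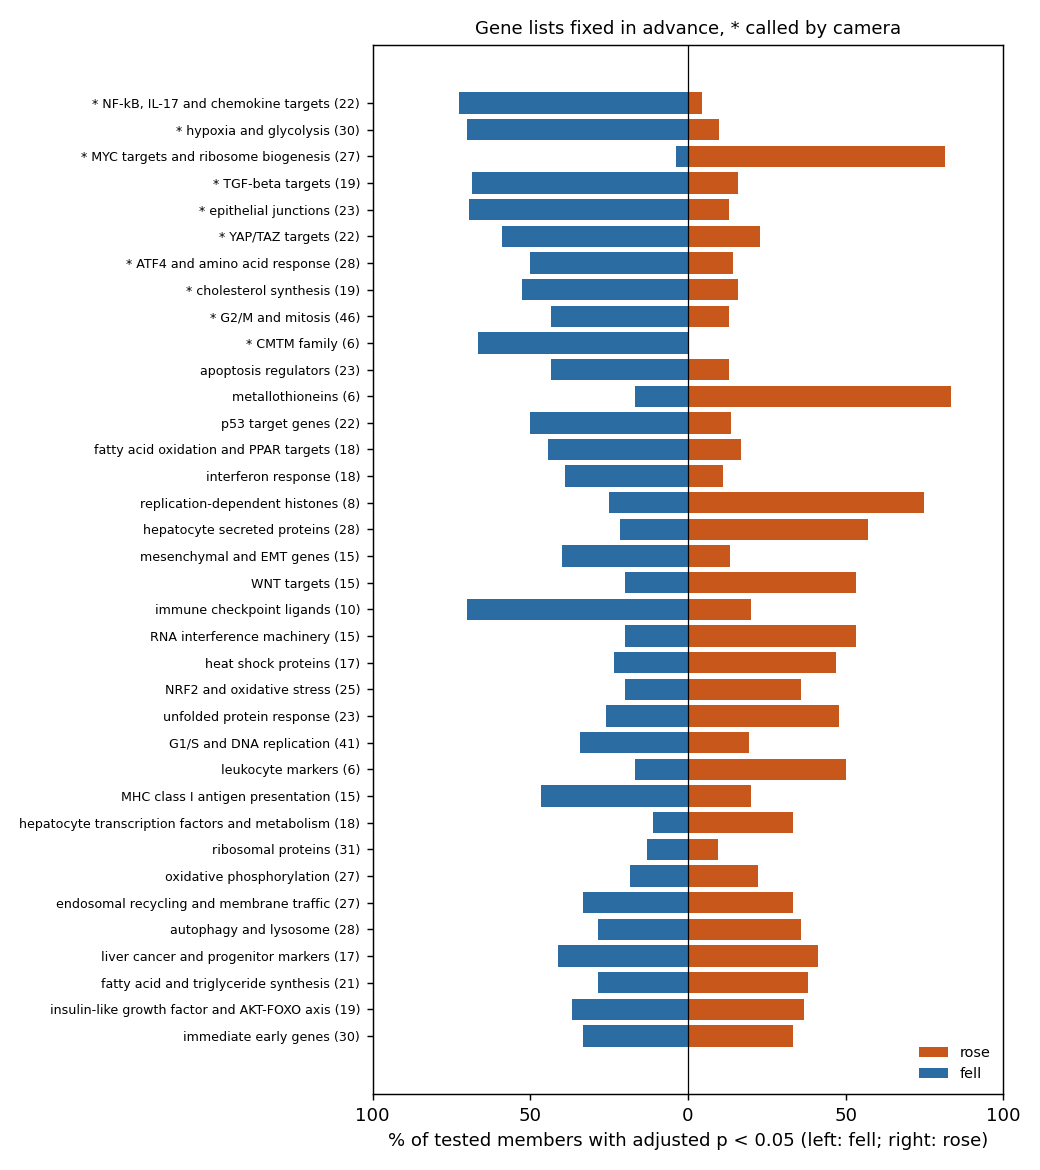
Percent of tested members (horizontal axis) that fell (blue, left) or rose (orange, right) at adjusted p under 0.05 in each of 36 gene lists, with the number of tested members in brackets and an asterisk for lists that passed camera with its preset correlation. NF-kB targets (16 of 22 lower) and hypoxia genes (21 of 30 lower) lie at the left and MYC targets (22 of 27 higher) at the right. Poly-A spike-in centring shifts all genes alike. With it the medians of 4 lists with an asterisk (G2/M, cholesterol, ATF4 and CMTM) turned from negative to positive, as did those of other lists without one. Of these 4 lists only G2/M lost its camera call.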

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

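The tests on GC-rich background, on the closeness of replicates, on the neighbouring chromosome segment, on the neighbours of the other lowered genes and on single probe sets, and the settings with poly-A spike-in centring and with unshared probe sets, were chosen only after the results were seen.

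A signal outside the tested genes was higher in the knockdown arrays: the 9 background control probe sets of the richest GC bins read 7.23 ± 0.01 in knockdown and 7.11 ± 0.08 in control arrays (SD, n = 3), a difference of 0.12 with all 9 higher (exact permutation p = 0.1, the smallest possible). Without control 1 the difference was 0.075, and without any other single array it was 0.12 to 0.15. Among 2376 tested probe sets with no gene name, 670 were higher and 571 lower in the knockdown, 5 and 18 of them by at least 2-fold. Over all 29839 probe sets tested, 8481 were higher and 7570 lower, 87 and 241 of them by at least 2-fold. The probe sets with no gene name thus split much as all probe sets did.

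Of 11488 tested genes, 6452 differed between the groups of 1 cell line. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the labelled one, gave as many genes (highest other 0) or as many genes changed at least 2-fold (126, highest other 0), but 10 splits are too few for a share under 0.05. The other splits mix arrays of both groups. Any difference between the groups, whatever its source, then widens their spread, so their counts of 0 tell little about that source. Background signal alone is argued against, since the within-group pair of arrays with the widest gap in GC-rich background (0.16, controls 1 and 2) differed over the tested genes by a median of 0.054, and the pair from different groups with the narrowest gap (0.047) by 0.137. Arrays of 1 culture, or of 1 RNA, would also give many small calls, and the median within-group SD of 0.047 cannot be told apart from either, since no repeat hybridization is labelled. An effect of the knockdown on transcripts stays open beside it. So does any difference in culture, RNA handling, labelling or hybridization that coincided with the groups. The labels name no batch, and the poly-A spike-ins read 8.02 in control and 7.86 in knockdown arrays.

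Genes that changed at least 2-fold were mostly lower: 92 of 126, or 73.0% (95% exact binomial interval 64.4% to 80.5%). Shared probe sets are argued against as the source, since unshared probe sets alone gave 73.6% (81 of 110). The share moved with the level of scaling, to 74.0% with median centring and 50.4% with poly-A spike-in centring (59 of 117, interval 41.0% to 59.8%). That centring adds the same shift to each gene, so a lower share follows from it and does not decide where the asymmetry comes from. Scaling, an effect of the knockdown and differences in handling that coincided with the groups all stay open.

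CMTM4 fell together with both tested neighbours, CMTM3 (-0.87) and DYNC1LI2 (-0.47). Both nearest tested neighbours were this low for 33 of 11429 genes (0.289%), CMTM4 included, and for 1 of the 91 other genes at least 2-fold lower (1.10%, 95% exact binomial interval 0.0278% to 5.97%), too few to exclude ordinary co-variation around a lowered gene. A single mismatched probe set is argued against by 8 of 8 probe sets of both neighbours lower in every knockdown array, and a lower copy number of a longer segment by TK2 (-0.013) and NAE1 (0.21). A local effect at the CMTM4 locus that lowers adjacent transcripts is a hypothesis left open by these tests, as are that co-variation, a deletion short enough to spare TK2 and NAE1 and off-target pairing of the hairpins, whose sequences were not used here.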

How the results depend on the processing

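Poly-A spike-in centring, unshared probe sets and the test against 1.2-fold were chosen after the data were seen. CMTM4 kept its direction and passed under each alternative run, from -1.83 (mean over its probe sets) to -2.71. Leaving out 1 array at a time gave 5813 to 6167 changed genes, 119 to 125 at 2-fold, 10 to 12 lists and -2.71 to -2.57 for CMTM4. Testing all probe sets gave 16051 calls (8481 higher, 7570 lower) and 328 at 2-fold, since 29839 features were tested, and 24 lists. In that setting the probe sets of 1 gene counted as separate list members. How much of the gain in lists came from such repeat readings was not tested. A 2-fold threshold gave 126 genes and the test against 1.2-fold 1255, by construction. Without a filter 17 lists passed (the cause was not tested); those gained were interferon response, p53 targets, apoptosis regulators, hepatocyte secreted proteins, fatty acid oxidation, metallothioneins and WNT targets. All probe sets also added these 7 and mesenchymal, unfolded protein response, histone, NRF2, heat shock, RNA interference and leukocyte lists. Unshared probe sets added p53 targets, apoptosis regulators and histones (13 lists), leaving out control replicate 3 added apoptosis regulators and metallothioneins, and poly-A spike-in centring added hepatocyte secreted proteins. With an estimated correlation 0 lists passed and with fry 29, which asks another question. All 10 lists passed under the other normalizations, filters and variance models, except G2/M with poly-A spike-in centring. Only 1 of the 10 splits gave 10 lists, and 10 splits are too few for a share under 0.05. The other splits, which mix arrays of both groups, called 1 to 7 lists with 0 genes past the threshold. Same-numbered arrays did not deviate together (correlations -0.228, 0.0198 and -0.0527), but deviations within groups of 3 arrays are a weak check and do not exclude pairing. With the replicate number as a block 6182 genes (3390 higher, 2792 lower), 126 at 2-fold and 10 lists passed, with CMTM4 at -2.66, and no named gene lost its call. Over the named genes 2789 values kept direction and side of the threshold, 23 lost the threshold and 8 reversed in sign. Of the 8 only RPS23, with the mean over probe sets, passed the threshold in its new direction (limma adjusted p = 0.00743). With poly-A spike-in centring the reversals were CMTM6 (0.068), CMTM8 (0.053), RPS15 (0.030), RPL13 (0.063) and FBLN1 (0.076), by the shift of all genes; with the mean over probe sets RPS23 (-0.11), and with unshared probe sets CREB3L2 (0.053) and RPS15 (0.11), as other probe sets were read. Of 3 groups of tested genes of about equal size by brightness, 38.7% of the dimmest and 66.6% of the brightest passed; whether signal over background accounts for this was not tested.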

Other observations

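The family comparison by symbol prefix was chosen after the results were seen. The gene lists were planned, and each count given was the same adjusted over the list alone unless another is stated.

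Growth factor and nutrient genes changed in both directions in the deposited scaling. Poly-A spike-in centring, which shifts all genes alike, moved each of their lists upward. Immediate early genes had 10 of 30 higher and 10 lower (list adjusted p = 0.917), against 17 higher and 5 lower with that centring (median 0.17 in place of 0.012): EGR1 (1.12), the ERK phosphatase DUSP5 (1.08) and FOS (0.47) rose, whereas KLF2 (-1.15), DUSP1 (-0.80) and JUNB (-0.37) fell. In the insulin-like growth factor and AKT-FOXO list 7 of 19 rose and 7 fell (8 and 7 adjusted over the list alone, adjusted p = 0.885), and with poly-A spike-in centring 12 were higher and 3 lower (median 0.23). Its members included IGFBP1 at 1.29 and TXNIP at 0.69, both known to be induced by FOXO factors or by glucose signals. The receptor IGF1R was at -0.55 and the PI3-kinase subunit PIK3R1 at -0.80. Of the probe sets of IGF1R and PIK3R1 above the filter, 4 of 5 and 4 of 7 passed in that direction. WNT targets had 8 of 15 higher and 3 lower (adjusted p = 0.167), or 11 and 3 with poly-A spike-in centring (median 0.30), and passed without a filter and with all probe sets tested, with LEF1 rising 2.64-fold (1.40), LGR5 by 0.55 and CCND1 by 0.57. For fatty acid and triglyceride synthesis 8 of 21 rose and 6 fell (adjusted p = 0.871), and the triglyceride enzymes GPAM (0.94) and DGAT2 (0.59) and the elongase ELOVL6 (0.57) rose as INSIG1 fell. For fatty acid oxidation 3 of 18 rose and 8 fell (adjusted p = 0.0889), with SLC25A20 at -0.38 and ACAA2 at -0.30. The list passed without a filter and with all probe sets tested, and its median of -0.083 became 0.079 with poly-A spike-in centring (8 higher, 4 lower). The fatty acid synthesis median of 0.0043 became -0.0038 with median centring and 0.17 with poly-A spike-in centring (15 higher, 3 lower).

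Stress and maintenance genes did not pass as lists in the deposited scaling with the filter at the 40th percentile and 1 probe set per gene, although several of these lists passed under other settings. Apoptosis regulators passed without a filter, with all probe sets tested, with unshared probe sets only and without control replicate 3, and p53 targets under the first 3 of these. Metallothioneins passed without a filter, with all probe sets and without control replicate 3, histones with all probe sets and with unshared probe sets, and NRF2, heat shock, unfolded protein response and RNA interference genes with all probe sets. Of 6 metallothionein list genes 5 rose and 1 fell (adjusted p = 0.0782), led by MT1X (0.65) and MT1E (0.52), and of 8 replication-dependent histones 6 rose and 2 fell (adjusted p = 0.0889), with H2AC6 at 1.01, H1-2 at -0.68 and H2BC21 at 0.86, the last from a control mean of 5.62 below the 40th percentile of each array, where the size of the change is uncertain. With poly-A spike-in centring 5 metallothionein list genes were higher and 0 lower (median 0.54), and 7 histones higher and 1 lower (median 0.59). Among 25 NRF2 targets 9 rose and 5 fell (adjusted p = 0.306), with ABCC2 (0.75) and SRXN1 (0.71) against GPX2 (-0.59). Among 22 p53 targets 3 rose and 11 fell (adjusted p = 0.0874) in this line, which lacks functional p53, with TNFRSF10B at 0.70 and SUSD6 at -0.73, and among 23 apoptosis regulators 3 rose and 10 fell (adjusted p = 0.0536), with BID at 0.41 and BCL2L1 at -0.40. The medians of the p53 list (-0.089) and the apoptosis list (-0.049) became 0.074 (10 higher, 7 lower) and 0.11 (7 higher, 5 lower) with poly-A spike-in centring. Heat shock genes had 8 of 17 higher and 4 lower (8 and 5 adjusted over the list alone, adjusted p = 0.295), with FKBP4 at 0.57, HSPB8 at -0.42 and CRYAB at -0.38. Unfolded protein response genes had 11 of 23 higher and 6 lower (adjusted p = 0.306), with DNAJB9 at 0.50 and CREB3L2 at -0.39. DERL1 of that list read -0.65 on its chosen probe set, but -0.03 on the brightest of its probe sets without a shared suffix. Of 15 RNA interference genes 8 rose and 3 fell (9 and 3 adjusted over the list alone, adjusted p = 0.245), with XPO5 at 0.34 and AGO4 at -0.57. For oxidative phosphorylation 6 of 27 rose and 5 fell (adjusted p = 0.765), for autophagy 10 of 28 rose and 8 fell (adjusted p = 0.790), and for endosomal recycling 9 of 27 rose and 9 fell (10 and 9 adjusted over the list alone, adjusted p = 0.783). Poly-A spike-in centring shifts all genes alike, and over all tested genes it gave 7668 higher and 1272 lower, with a median of 0.19. Lists with near-even splits had to turn mostly higher with it, which is no result about those lists. It gave 24 higher and 0 lower for oxidative phosphorylation (median 0.19), 19 and 6 for autophagy (0.20) and 17 and 2 for endosomal recycling (0.17). The same centring gave 19 higher and 3 lower for NRF2 targets (median 0.23), 13 and 2 for heat shock genes (0.26), 17 and 4 for unfolded protein response genes (0.23) and 12 and 2 for RNA interference genes (0.29).

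Among the 36 tested lists, 2 had summaries that differed in sign: endosomal recycling had a median of 0.0099, a mean of -0.0017 and a test direction of lower, and immediate early genes a median of 0.012, a mean of 0.023 and a test direction of lower. The fibroblast list, too short to be tested, had a median of 0.12 and a mean of -0.0013. Among 72 groups of genes that share a symbol prefix, each with at least 15 tested members, 0 passed camera after adjustment (smallest adjusted p = 0.515) and 5 had an unadjusted p under 0.05. With an estimated correlation 0 passed.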
